A study of Mus musculus with 18 samples.

How the data were processed

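Islets came from C57BL/6 mice of both sexes aged 16 weeks, and their total RNA was labelled with biotin from 250 ng and measured on 18 single-colour Affymetrix whole-transcript arrays. Knockout mice carried floxed TRAF2 or TRAF3 alleles and RIP-Cre, a Cre recombinase driven by the rat insulin promoter, and the controls were littermates with floxed alleles, for which neither the floxed gene nor the absence of Cre is stated. The genotypes follow the sample labels, since the text of the series writes TRAF2 for both knockouts. Each genotype was studied on chow and after 8 weeks on a high-fat diet (HFD) with 45% of the energy as fat, begun at 8 weeks of age. This gave 6 groups of 3 arrays, and the labels do not say that each sample is 1 separate animal.

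The authors deposited 1 value per probe set and array on the log2 scale, and their processing notes name RMA (background correction, quantile normalization between arrays and a summary per probe set) and limma, without versions. The log2 base was checked against the values: the arrays had medians between 4.80 and 4.96 and maxima between 13.5 and 13.6. Whether all 18 arrays were normalized together is not stated, nor is a genome build. The table held 41345 probe sets, none with a missing value, and no pair of columns was identical. Values were used as deposited. For arrays of this kind the number of samples limits the precision.

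Probe sets were given gene symbols from the platform's annotation: 23521 probe sets had exactly 1 symbol, 1814 had several and 16010 had none in the table used here. Probe sets with exactly 1 symbol were kept, and of the 1082 genes with more than 1 probe set the one with the highest mean over all arrays was used, which left 22180 genes. The transcript of TRAF3 is not reported here. No filter on signal level was applied.

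Differential expression was tested with limma 3.58.1 in R 4.3.3, with lmFit and eBayes defaults on 1 fit of 6 group means, which gave 12 residual and 3.69 prior degrees of freedom. There were 11 contrasts: each knockout against control on each diet, both knockouts against control averaged over diets, HFD against chow within each genotype, the knockout by diet interaction of each knockout, and the TRAF2 against the TRAF3 knockout averaged over diets. Tests were two-sided, p-values were adjusted by Benjamini and Hochberg over all genes within a contrast, and an adjusted p under 0.05 counted as passing. A standard error (SE) beside a log2 fold change is limma's moderated one, and a standard deviation (SD) is that of 3 arrays. The p-values measure the spread between samples.

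The contrasts, the gene lists, the rule for named genes and the alternatives were chosen before the data were examined, apart from the exceptions named here and in the closing section. Of 26 lists with 442 genes, 395 genes were measured and 24 lists were tested as sets with camera at a preset inter-gene correlation of 0.01. Camera with a correlation estimated per list and the directional test of fry were run beside it. Camera compares the genes of a list with all other genes, whereas fry asks whether they move, on balance, in 1 direction. Camera p-values were adjusted over the 24 lists. For each list the number of genes passing is given over all genes and adjusted over the list alone. A list score is the mean over the list's genes of each gene's deviation from its mean over all arrays, on the log2 scale.

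Named genes followed a rule: the targeted genes, the 10 largest rises and 10 largest falls that passed in the combined comparison of both knockouts and the 5 of each in the others, and from each described list up to 4 members that passed with the largest changes, or its first 2 measured members where none passed. Placeholder symbols (such as those starting Gm or LOC, or ending Rik) and olfactory, immunoglobulin and small RNA genes were counted but not named. A largest rise, fall or difference is therefore the largest among the genes that could be named. Malat1, Ins2 on chow, and the use of Xist and a Y-linked gene per array, fall outside this rule and were chosen after their values were seen.

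Alternatives changed 1 choice at a time: each array centred on its median, quantile normalization applied again, eBayes with trend and robust, dim genes left out (11090 genes kept), every probe set of the table, only the samples compared, the replicate number as a block, a sex score or an acinar score as a covariate, and each of the 18 arrays left out in turn for every comparison, where an array outside a comparison acts through the pooled spread alone. A ductal score as a covariate, leaving out the lymphocyte-rich arrays (chow TRAF2 knockout 1 and HFD TRAF3 knockout 2), and leaving out chow control 3 with chow TRAF2 knockout 1 were chosen after seeing the data. Counts were also taken under other splits of the samples, all 10 for 3 arrays against 3 and 100 drawn with a fixed seed elsewhere. Since TRAF2 and TRAF3 knockouts share controls within a diet, the correlation that sharing alone gives was simulated in 100 data sets without any effect.

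The fit was tested on simulated data with 22180 genes of which 200 were changed. In a comparison of 3 arrays with 3 it recovered 28.8% of genes changed 1.5-fold, 71.8% of those changed 2-fold and 97.1% of those changed 4-fold, with 9 false calls. In the comparison of both knockouts with control it recovered 63.3%, 90.1% and 100% of them, with 6 false calls, and no gene was called in the wrong direction in either. In the simulated set tests, 3 of 3 shifted lists were recovered with 0 false calls by camera. The simulated genes were drawn independently, so this says nothing about false calls for lists whose genes vary together.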

Results

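Transcripts of pancreatic islets were measured on 18 arrays, with 3 arrays in each of 6 groups: floxed littermate controls, beta cell TRAF2 knockouts and beta cell TRAF3 knockouts, each on chow and on high-fat diet (HFD). TRAF2 and TRAF3 are adaptor proteins that restrain NF-kB inducing kinase (NIK), the kinase of the non-canonical NF-kB pathway, and the series was made to learn what constitutive NIK activity does in beta cells. Within groups the arrays correlated at 0.9595 to 0.993 across genes, which are not independent replicates. Some arrays stood apart from their group. In chow control 3, Tph1 read 8.30 against 4.15 and 4.12 in the other chow controls. Chow control 1, the 1 female array of its group, had a ductal score of -0.976 against 0.33 and 0.195 in the other chow controls. Its mean correlation with its group (0.9772) was the lowest of those 3 arrays. Chow TRAF2 knockout 1 had the highest lymphocyte score (1.85, against -0.32 and -0.97 in the others of its group), read 9.26 for the interferon regulator Irf7 against 6.46 and 6.33, was the 1 female array of its group, and was closest to chow TRAF3 knockout 1 (r = 0.987 across genes), also a female array. HFD TRAF3 knockout 2 had a lymphocyte score of 1.69. HFD TRAF3 knockout 3 had the lowest mean correlation with its group among its 3 arrays (0.9655) and was closest to chow control 3, HFD TRAF3 knockout 1 was closest to chow TRAF2 knockout 3, and chow control 3 to chow TRAF2 knockout 2 (r = 0.9865, 0.9862 and 0.9923). By Xist and the Y-linked gene Eif2s3y, each chow group held 1 female and 2 male arrays, the HFD controls 3 female arrays and each HFD knockout group 2 female and 1 male. No background level was set, and in 34 of 245 named changes between 2 groups that passed, the mean of the lower group was below the median of every array, so that the size of those changes is uncertain.

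Traf2, the gene deleted in beta cells of 1 of the mouse lines, was measured by probe set 17382626, which covers the whole transcript and so does not check the deletion of the floxed part. It read 7.18 ± 0.15 (SD, n = 3) in chow controls and 7.32 ± 0.16 in chow TRAF2 knockouts (log2 difference 0.14 ± 0.14 SE, adjusted p = 0.98). On HFD it read 6.46 to 7.03 in controls and 6.90 to 7.15 in TRAF2 knockouts (0.17 ± 0.14, adjusted p = 0.975). The transcript did not pass the test in any of the 11 comparisons.

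**Figure D1:**
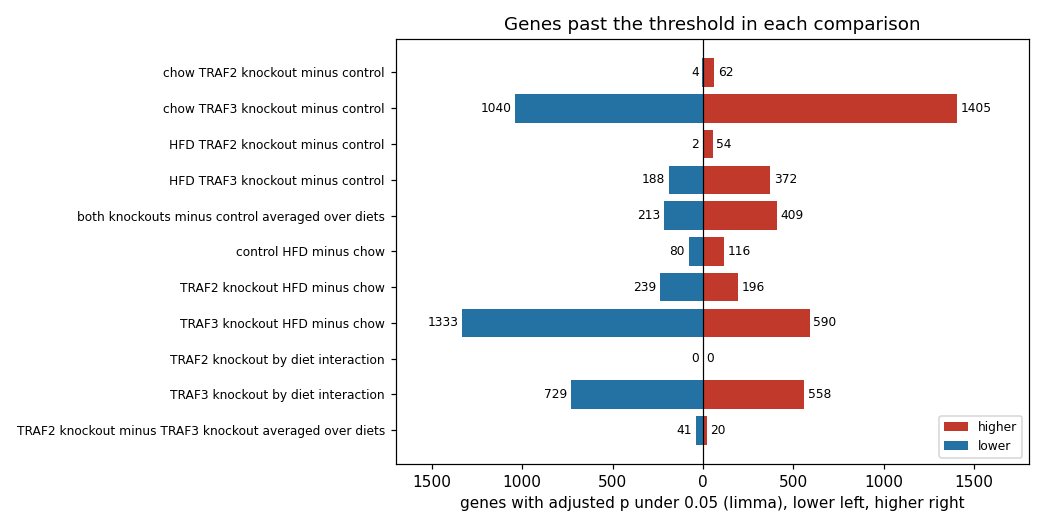
Number of genes past the threshold in each of the 11 comparisons, with genes lower to the left and genes higher to the right of 0 on the horizontal axis. The chow TRAF3 knockout had 1405 genes higher and 1040 lower, against 62 and 4 in the chow TRAF2 knockout.

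Across both diets, Tph1 and Lrrc55 had the largest differences between knockout and control islets. Tph1 (probe set 17491163), the rate-limiting enzyme of serotonin synthesis that rises in islets in pregnancy, was 26.9-fold higher in the knockouts (log2 fold change 4.75 ± 0.54 SE, adjusted p = 0.000154). It lay between 6.86 and 11.37 in the 12 knockout arrays and between 3.76 and 4.55 in the controls, apart from chow control 3 at 8.30. Lrrc55 (probe set 17387565), an auxiliary subunit of BK potassium channels, was 18.2-fold higher (4.18 ± 0.36, adjusted p = 2.79e-05), with 7.78 to 9.46 in the knockout arrays and at most 7.12 in the controls, while its other probe set had a log2 fold change of 0.87. The tight junction gene Cldn8 was 9.52-fold higher, the collectin Sftpd 8.91-fold, the guanylate-binding protein Gbp8 7.90-fold, the Ras activator Rasgrp1 7.88-fold and Crispld2 7.64-fold. Syt10, Fbxw24 and Gstt4 rose 7.04-fold, 6.96-fold and 6.25-fold, and the adjusted p of all these lay between 1.74e-05 and 0.00358. Control means of Syt10 (4.73 on chow, 4.51 on HFD) lay below the median of every array. So did the HFD control means of Tph1, Lrrc55 and Gbp8 (3.89 to 4.79). The size of these rises is uncertain, as is that of any other gene here whose controls read as low. Among the genes that fell, Vsnl1, a calcium sensor, fell by 1.65 ± 0.31 on the log2 scale (adjusted p = 0.00775). Hapln1, Pappa2, Insrr, Acta2, Sult1d1, Tnr, Abcd2, Calb1 and C8b had log2 fold changes from -1.34 to -1.06 and adjusted p from 0.00333 to 0.0495. Without chow control 3 the log2 fold changes of Tph1 and Cldn8 were 5.44 and 3.93. In all, limma called 622 of 22180 genes, 409 higher and 213 lower. The count was 282 with the ductal score as a covariate, of which 225 were among the 622, and all 622 kept their sign with a median size of 0.56 (median SE 0.14) against 0.65 (0.13). It was 1322 with the acinar score. It was 389 without HFD control 1 and 342 without chow control 1, and of 53 named genes that passed, 36 kept their call whichever array was left out.

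**Figure D2:**
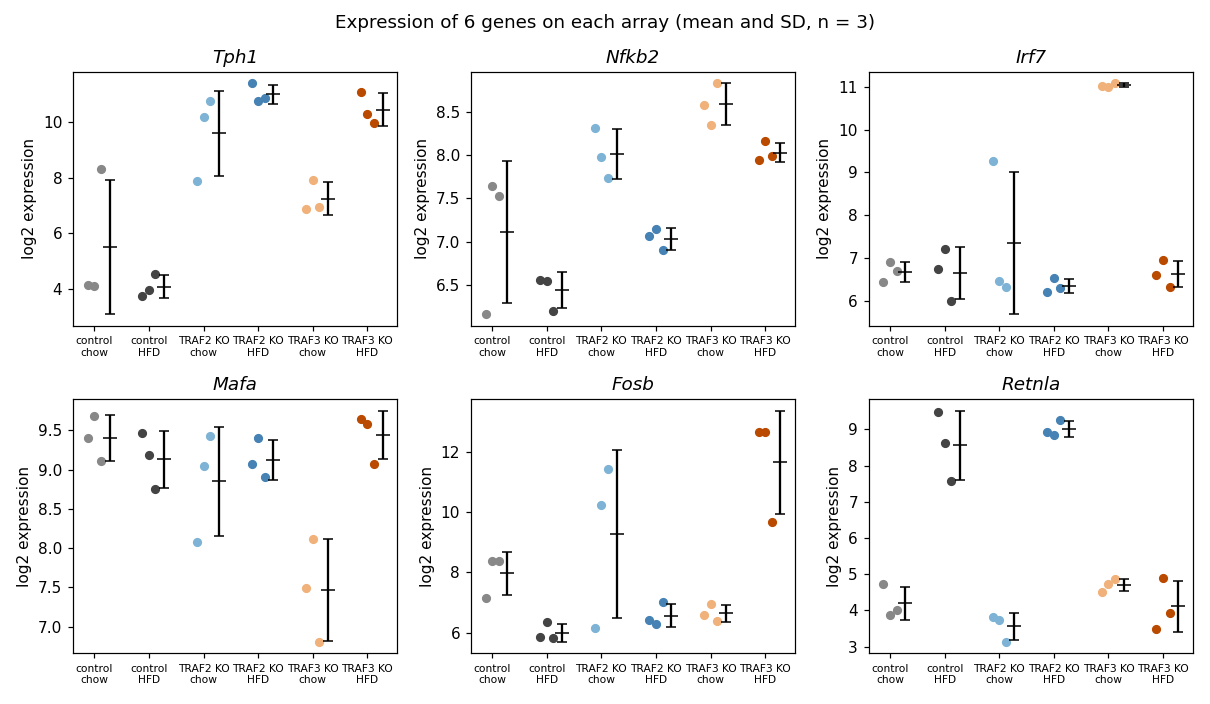
Log2 expression (vertical axis) of Tph1, Nfkb2, Irf7, Mafa, Fosb and Retnla on every array, by genotype and diet (horizontal axis), with the group mean and SD (n = 3) in black. Tph1 is at 6.86 or above in every knockout array and at 8.30 in chow control 3, Irf7 stands at 10.99 to 11.08 in the chow TRAF3 knockouts, and Retnla is at 7.57 or above in HFD controls and HFD TRAF2 knockouts and at 4.89 or below elsewhere.

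Grouped by list, all 12 measured lactogen and growth hormone responsive genes rose in the knockouts over both diets, as did 12 adjusted over the list alone. The decoy receptor Tnfrsf11b was 5.45-fold and the matrix protein Matn2 4.93-fold higher, and the list score was 1.88 ± 0.20 (SE) higher (camera adjusted p = 8.77e-30, and adjusted p = 0.00674 with an estimated correlation). The score of chow control 3 was -0.26, against -1.43 and -1.53 in the other chow controls. Of 17 NF-kB components and feedback genes, 10 rose (13 adjusted over the list alone). Tnfaip3, a feedback inhibitor, was 2.37-fold higher, Nfkb2, which encodes the precursor processed under NIK, 2.21-fold, Rel 2.02-fold and Bcl3 1.94-fold (list adjusted p = 5.93e-17, and adjusted p = 0.0347 with an estimated correlation). No other list kept its call with an estimated correlation. Of the interferon-stimulated genes 7 of 22 rose (20 adjusted over the list alone), Gbp3 by 2.18-fold and Usp18 by 1.94-fold (adjusted p = 1.37e-17, and adjusted p = 0.0768 with an estimated correlation). Of the immediate early genes 6 of 12 rose (12 adjusted over the list alone), among them Ier3 at 3.09-fold (adjusted p = 4.23e-13, and adjusted p = 0.0768 with an estimated correlation).

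Other lists passed in this combined comparison only at the preset correlation. Of 28 chemokines, cytokines and adhesion molecules 5 rose, with the cytokine Il6 5.10-fold and the T cell attractant Cxcl10 4.61-fold higher, at a log2 fold change of 1.62 without chow control 1 (12 rose and 1 fell adjusted over the list alone; adjusted p = 0.179 with an estimated correlation). Of 11 hypoxia and glycolysis genes 2 rose (6 adjusted over the list alone), with the glucose transporter Slc2a1 2.39-fold higher by 1 of its 2 probe sets (log2 fold change 0.09 by the other), and of 13 apoptosis and survival genes 2 rose (3 adjusted over the list alone), with the cell cycle inhibitor Cdkn1a 2.46-fold higher (adjusted p = 0.179 for both with an estimated correlation). Antigen processing had 2 of 17 genes higher (7 adjusted over the list alone), Tap1 and Tap2 (adjusted p = 0.266 with an estimated correlation). The disallowed and dedifferentiation list had 1 of 14 (3 adjusted over the list alone) and lipogenesis and cholesterol synthesis 1 of 17 (4 adjusted over the list alone), with adjusted p = 0.223 and adjusted p = 0.318 with an estimated correlation. ER stress and the unfolded protein response had 0 of 21 by limma over all genes and 2 adjusted over the list alone (adjusted p = 0.482 with an estimated correlation). Beta cell identity and insulin secretion was lower as a list, with Slc30a8, the zinc transporter of insulin granules, the 1 of 29 genes that fell (6 adjusted over the list alone; adjusted p = 0.422 with an estimated correlation). Of the other islet endocrine genes 2 of 11 fell (7 adjusted over the list alone), Slc7a2 and Irx2 (adjusted p = 0.19 with an estimated correlation).

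Markers of other cells moved beside these. Ductal markers were higher as a list, with Cftr 2.65-fold higher as the 1 of 10 that passed (4 adjusted over the list alone; adjusted p = 0.179 with an estimated correlation). Lymphocyte markers were higher and acinar markers lower as lists with no gene passing by limma on either count, and their adjusted p = 0.482 and adjusted p = 0.422 with an estimated correlation. The remaining 8 lists did not pass at the preset correlation, where macrophages and other myeloid cells had an adjusted p of 0.087, stellate cells, fibroblasts and pericytes 0.367, adipocytes 0.397 and oxidative phosphorylation 0.528. Endothelial cells, Schwann and neural cells and proliferation each had 0.59, and fatty acid oxidation and PPAR targets 0.94.

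**Figure D3:**
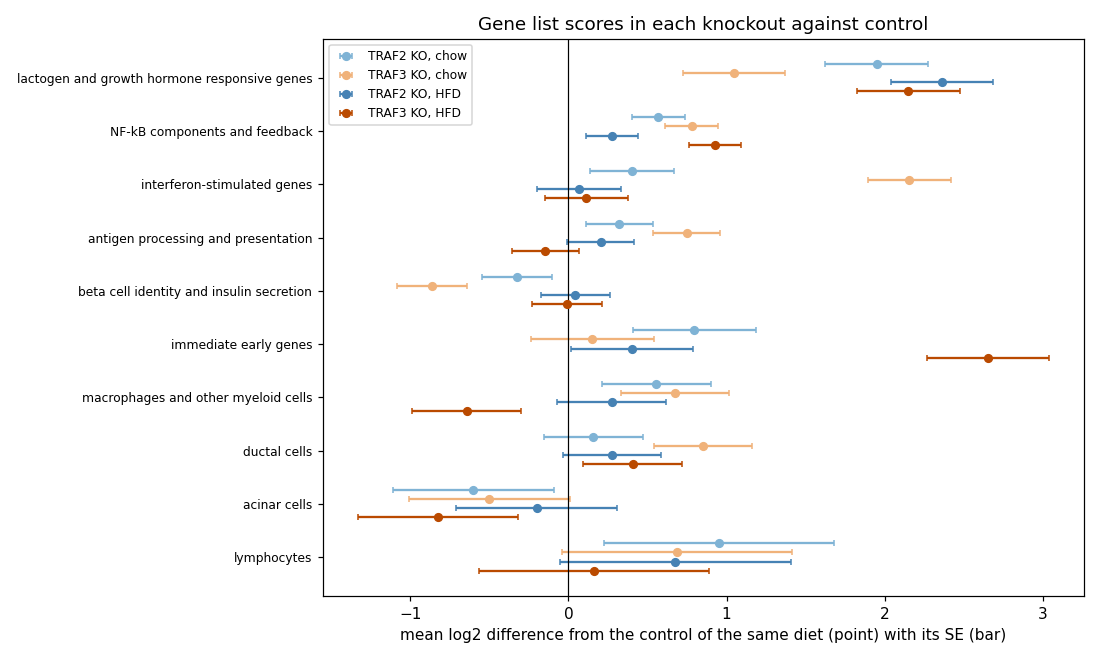
Difference in list score between each knockout and the control of the same diet (horizontal axis, mean log2 difference with its SE) for the gene lists named on the vertical axis. The lactogen list is higher by 1.05 to 2.36 in every knockout, the interferon list by 2.15 in the chow TRAF3 knockout against 0.07 to 0.40 elsewhere, and the immediate early list by 2.65 in the HFD TRAF3 knockout.

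On chow, TRAF2 knockout islets differed from controls mainly in genes that were higher. Cldn8 was 17.7-fold higher (4.15 ± 0.79, adjusted p = 0.031), Lrrc55 13.8-fold (3.78 ± 0.58, adjusted p = 0.00952), Crispld2 10.2-fold (3.36 ± 0.45, adjusted p = 0.00523), Syt10 9.19-fold (adjusted p = 0.00427) and Rasgrp1 8.91-fold (adjusted p = 0.0125), with n = 3 per group. Without chow control 3 the log2 fold changes were 5.51 for Cldn8, 4.74 for Lrrc55, 4.10 for Crispld2 and 3.97 for Rasgrp1, and they were 3.15 for Cldn8 and 2.95 for Lrrc55 without chow control 2 and 2.76 for Crispld2 without chow control 1. The other probe set of Lrrc55 was at 0.80. The genes that fell were the ephrin receptor Epha7, the kinase Nuak1, the melanosome adaptor Mlph and Foxa2, a transcription factor of endoderm and islets, which fell by 0.68 ± 0.12 on the log2 scale (adjusted p = 0.0277). Each of these 4 was lower in all 3 knockouts than in all 3 controls. Of the lactogen list 7 of 12 rose (12 adjusted over the list alone), Gbp8 by 8.91-fold (4.02 on the log2 scale without chow control 3), the muscle gene Neb by 6.31-fold and the STAT5 target Socs2 by 2.68-fold, with its other probe set at 0.90 on the log2 scale (adjusted p = 1.29e-33, and adjusted p = 0.00398 with an estimated correlation). Of the NF-kB list Birc3, an inhibitor of apoptosis that also restrains NIK, rose 1.99-fold and Tnip1 1.68-fold (2 of 17, and 8 adjusted over the list alone; adjusted p = 0.0972 with an estimated correlation). Another 15 lists passed at the preset correlation, and with an estimated one their adjusted p lay between 0.213 and 0.489. The lymphocyte score was 0.95 ± 0.73 higher, chow TRAF2 knockout 1 having most of it. Limma called 66 genes, 62 higher and 4 lower, out of 1429 with an unadjusted p under 0.05. It called 0 with only the 6 arrays compared in the fit and 100 with the ductal score as a covariate. It called 10 genes without chow TRAF2 knockout 3, 22 without chow control 1 and 24 without chow control 2, and Crispld2 and Syt10 were the 2 of 16 named genes called whichever array was left out.

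On chow, TRAF3 knockout islets had higher interferon-stimulated and cytokine genes and lower beta cell genes. Irf7 (probe set 17497813), a master regulator of the interferon response, was 20.5-fold higher (4.36 ± 0.54, adjusted p = 0.000439), at 10.99 to 11.08 in the 3 knockouts and 6.44 to 6.91 in the controls. The antiviral tetherin Bst2 was 12.5-fold higher (3.64 ± 0.31, adjusted p = 3.26e-05) and 20 of 22 interferon-stimulated genes rose (21 adjusted over the list alone; list adjusted p = 1.19e-27, and adjusted p = 0.072 with an estimated correlation). The acute phase gene Serpina3n was higher by 4.53 ± 0.81 on the log2 scale, Il6 19.1-fold and the keratin Krt20 18.2-fold, and without chow control 1 Serpina3n and Il6 were at 3.94 and 3.40 on the log2 scale. The neutrophil attractant Cxcl3 also rose, from 1.93 to 2.79 in controls, a range so low that the size of the rise is uncertain, to 5.64 to 7.32. Of the chemokine and cytokine list 13 of 28 rose and 1 fell (16 and 1 adjusted over the list alone), with the monocyte attractant Ccl2 15.2-fold and the T cell attractant Ccl5 13.9-fold higher (adjusted p = 0.177 with an estimated correlation). Of the antigen processing list 10 of 17 rose (11 rose and 1 fell adjusted over the list alone), the peptide transporter Tap1 by 5.72-fold and the immunoproteasome subunit Psmb8 by 3.07-fold (adjusted p = 0.177 with an estimated correlation). Of the NF-kB list 9 of 17 rose (11 adjusted over the list alone), Birc3 by 3.09-fold and Nfkb2 by 2.78-fold (adjusted p = 0.177 with an estimated correlation).

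Beta cell genes went the other way in the chow TRAF3 knockouts, where 14 of 29 fell (20 adjusted over the list alone; list adjusted p = 4.38e-13, and adjusted p = 0.177 with an estimated correlation). Slc2a2, the glucose transporter of rodent beta cells, fell by 2.97 ± 0.52 on the log2 scale (adjusted p = 0.00313), from 10.93 to 11.99 in controls to 7.99 to 9.05 in the knockouts. Ucn3, a marker of mature beta cells, fell by 2.04 ± 0.37, Slc30a8 fell by 1.98 ± 0.33, and Mafa (probe set 17318160), a transcription factor of mature beta cells, fell by 1.93 ± 0.34 (adjusted p = 0.00307). Ins2 read 11.26 ± 0.25 against 11.93 ± 0.12 and fell by 0.67 ± 0.17 (adjusted p = 0.0218). The insulin receptor-related receptor Insrr, Vsnl1, the protease Pappa2 and Serpini2, a serpin of exocrine pancreas, were among the 5 largest falls with Slc2a2, at log2 fold changes of -3.96 to -2.88. Among genes usually kept silent in beta cells, the lactate genes Slc16a1 and Ldha were 4.38-fold and 2.81-fold higher (4 of 14 in the list, 5 adjusted over the list alone; adjusted p = 0.177 with an estimated correlation). Of the other islet endocrine genes 3 of 11 fell, Slc7a2, Ghrl and Ttr (7 adjusted over the list alone; adjusted p = 0.177 with an estimated correlation). The lipid droplet gene Plin2 was 6.18-fold higher with 4 of 17 fatty acid genes (4 adjusted over the list alone; adjusted p = 0.283 with an estimated correlation). The hypoxia gene Car9 was 6.08-fold higher by 1 of its 2 probe sets (0.20 on the log2 scale by the other), with 4 of 11 up and 1 down (8 and 1 adjusted over the list alone), and 5 of 13 apoptosis genes (6 adjusted over the list alone), 5 of 20 oxidative phosphorylation genes (6 adjusted over the list alone) and 6 of 12 lactogen genes (8 adjusted over the list alone) rose (adjusted p = 0.177 for each with an estimated correlation).

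Other cell markers differed in the same arrays. Ductal scores were 0.65, 0.45 and 1.00 in the chow TRAF3 knockouts and -0.98, 0.33 and 0.20 in their controls (Anxa3 rose, 1 of 10, and 2 adjusted over the list alone; adjusted p = 0.177 with an estimated correlation). Of the myeloid markers 3 of 18 rose, Cd68, Cd14 and Fcer1g (5 adjusted over the list alone; adjusted p = 0.445 with an estimated correlation). Acinar markers were lower as a list with 0 of 21 passing by limma on either count (adjusted p = 0.789 with an estimated correlation). Limma called 2445 genes in this comparison, 1405 higher and 1040 lower. With the ductal score as a covariate it called 190, of which 176 were among the 2445, although all 2445 kept their sign and the median size of their log2 fold changes went from 0.80 to 0.56 with a median SE of 0.19 before and 0.21 after. Irf7 (adjusted p = 0.0184), Bst2 and Ccl2 still passed with that covariate, while Slc2a2 (-1.93 ± 0.52, adjusted p = 0.0974), Mafa (-1.44 ± 0.39, adjusted p = 0.0966) and Nfkb2 (0.82 ± 0.26, adjusted p = 0.142) did not. The count was 4150 with the acinar score. It was 1172 without chow TRAF3 knockout 1, 786 without chow TRAF3 knockout 3, 1117 without chow control 1 and 1580 without chow control 2. Of 70 named genes that passed, 39 kept their call whichever array was left out.

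On HFD, TRAF2 knockout islets had higher lactogen responsive genes. Tph1 was higher by 6.88 ± 0.88 on the log2 scale (adjusted p = 0.00241), at 10.75 to 11.37 in the 3 knockouts and 3.76 to 4.55 in the controls, and since the controls lay below the array medians the fold is uncertain. So is that of Lrrc55, which was 32.1-fold higher (adjusted p = 0.00132), with its other probe set at 1.01 on the log2 scale. Sftpd was 16.8-fold higher and Syt10 11.5-fold, and Gbp8 was higher by 3.59 ± 0.53 on the log2 scale. The gene named among the 2 that fell was Nhs, which fell by 0.53 ± 0.10 (adjusted p = 0.0463). Of the lactogen list 9 of 12 rose (12 adjusted over the list alone; adjusted p = 1.5e-38, and adjusted p = 0.00215 with an estimated correlation). Ngfr, a neurotrophin receptor, rose 2.49-fold as the 1 of 7 Schwann and neural genes that passed (1 adjusted over the list alone), and that list did not pass by camera. No NF-kB gene passed over all genes by limma and 1 of 17 did adjusted over the list alone, with a list score 0.28 ± 0.17 higher (adjusted p = 0.000714, and adjusted p = 0.648 with an estimated correlation). Another 8 lists passed at the preset correlation, with adjusted p from 0.46 to 0.702 with an estimated correlation. Limma called 56 genes, 54 higher and 2 lower, and 102 with the ductal score as a covariate. It called 24, 32 and 29 without HFD TRAF2 knockout 1, 2 and 3, 31 without HFD control 1 20 without HFD control 3 and 92 without HFD TRAF3 knockout 3, and 6 of 9 named genes kept their call whichever array was left out.

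On HFD, TRAF3 knockout islets had higher lactogen responsive, immediate early and NF-kB genes. Tph1 was higher by 6.33 ± 0.88 on the log2 scale (adjusted p = 0.00154) and Lrrc55 by 5.04 ± 0.58 (adjusted p = 0.000583; 1.18 by its other probe set), against the same low control values, with 10 of 12 lactogen genes up (11 adjusted over the list alone; adjusted p = 0.0195 with an estimated correlation). All 12 immediate early genes rose (12 adjusted over the list alone; adjusted p = 6.79e-24, and adjusted p = 0.0195 with an estimated correlation). Fosb (probe set 17487211), a subunit of the AP-1 transcription factor, was 50.2-fold higher (5.65 ± 0.99, adjusted p = 0.00607), at 9.68 to 12.65 in the knockouts and 5.83 to 6.34 in the controls. Jun, another AP-1 subunit, was 8.83-fold higher (adjusted p = 0.000194) and Npas4, a calcium-induced transcription factor, 24.9-fold. Of the NF-kB list 10 of 17 rose (12 adjusted over the list alone), Rel by 4.10-fold, Tnfaip3 by 3.91-fold and Nfkb2 by 3.02-fold (adjusted p = 1.06e-13, and adjusted p = 0.0477 with an estimated correlation). Without HFD TRAF3 knockout 3 the log2 fold changes of Fosb, Npas4 and Tnfaip3 were 6.64, 5.45 and 2.63.

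The stress gene Atf3 was 19.2-fold higher in the same comparison with Ddit3 and Atf4, members of 4 of 21 ER stress genes that rose (7 adjusted over the list alone; adjusted p = 0.47 with an estimated correlation). Retnla (probe set 17326069), a gene of alternatively activated macrophages, fell by 4.45 ± 0.41 (adjusted p = 0.000194), and Folr2, F13a1 and the lectin Cd209d had log2 fold changes of -3.08 to -2.79. These arrays also stood apart from both other HFD groups in diet-responsive genes. This was read in 115 genes that differed between HFD and chow in the same direction in controls and TRAF2 knockouts. On a scale from 0 (chow) to 1 (HFD) the HFD TRAF3 knockouts stood at 0.270, 0.299 and 0.0736. The other HFD arrays stood at 0.908 to 1.04 by construction, since they helped to choose these genes and to set the scale. In the HFD TRAF3 knockouts the nuclear RNAs Neat1 and Malat1 read 7.85 ± 0.44 and 10.52 ± 0.11, against 6.14 ± 0.17 and 9.79 ± 0.14 in HFD controls (adjusted p = 0.00118 and 0.146). The smooth muscle gene Acta2 fell by 2.58 ± 0.39. Of the myeloid list Mrc1 and Adgre1 fell (2 of 18, and 5 adjusted over the list alone; adjusted p = 0.47 with an estimated correlation), and of the stellate list Acta2 and Tagln (2 of 15, and 2 adjusted over the list alone; adjusted p = 0.606 with an estimated correlation). Acinar markers were lower with 0 of 21 passing by limma on either count (adjusted p = 0.52 with an estimated correlation). The acinar scores were -0.126, -1.451 and 0.792, against 0.381, 0.474 and 0.839 in HFD controls, so HFD TRAF3 knockout 2 held most of the fall. Beta cell genes did not pass (0 of 29 by limma on either count; list adjusted p = 0.713). Another 6 lists passed at the preset correlation, with adjusted p from 0.109 to 0.585 with an estimated correlation. Limma called 560 genes, 372 higher and 188 lower. The count was 144 with only the 6 arrays compared in the fit, 873 with the acinar score, 890 with the ductal score and 367 without the lymphocyte-rich arrays. It was 337 without HFD TRAF3 knockout 1, 249 without HFD TRAF3 knockout 2, 312 without HFD control 2 and 291 without HFD control 3, and 21 of 37 named genes kept their call whichever array was left out.

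In control islets, Retnla had the largest rise on HFD. It was 20.5-fold higher (4.36 ± 0.41, adjusted p = 0.000123), at 7.57 to 9.49 against 3.86 to 4.73 on chow. The lysozyme Lyz1 was 11.5-fold higher, Cd209d 10.7-fold, the folate receptor Folr2 10.6-fold and the mannose receptor Mrc1 8.74-fold (adjusted p from 0.00102 to 0.0231). Of the myeloid list 7 of 18 rose (14 adjusted over the list alone; adjusted p = 5.47e-14, and adjusted p = 0.169 with an estimated correlation). Acta2, at 4.96-fold, and Tagln rose among 15 stellate and pericyte markers (2 adjusted over the list alone; adjusted p = 0.534 with an estimated correlation), and the fatty acid transporter Cd36 was 4.25-fold higher. The nuclear long non-coding RNA Neat1 fell by 1.76 ± 0.23 (adjusted p = 0.0024), Jun fell by 1.58 ± 0.30, the hormone Stc1 fell by 2.17 ± 0.48 (-2.99 without chow control 1), and the neuropeptide Vip and the kinase Plk3 fell too (adjusted p = 0.0491 and 0.0415). Oxidative phosphorylation genes were higher as a list (2 of 20 rose, and 5 adjusted over the list alone; adjusted p = 0.169 with an estimated correlation) and immediate early genes lower (1 of 12 fell, and 2 adjusted over the list alone; adjusted p = 0.534 with an estimated correlation). In all, 8 lists were higher and 5 lower at the preset correlation, and the other 9 had adjusted p from 0.534 to 0.66 with an estimated correlation. Limma called 196 genes, 116 higher and 80 lower. The HFD controls were all female arrays, and the count was 48 with the sex score as a covariate, of which 47 were among the 196, while all 196 kept their sign with a median size of 1.07 (median SE 0.22) against 1.11 (0.21). It was 306 with dim genes left out, 78 with only the 6 arrays compared in the fit, 382 with the acinar score, 831 with the ductal score and 466 without the lymphocyte-rich arrays. It was 115, 40 and 89 without HFD control 1, 2 and 3, and 603, 19 and 55 without chow control 1, 2 and 3. Through the pooled spread it was also 362 without chow TRAF2 knockout 1, 109 without chow TRAF3 knockout 1, 117 and 126 without HFD TRAF2 knockout 2 and 3 and 345 without HFD TRAF3 knockout 3, and 7 of 21 named genes kept their call whichever array was left out.

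In TRAF2 knockout islets Retnla again had the largest rise on HFD. It was 43.9-fold higher (5.46 ± 0.41, adjusted p = 5.52e-06), Cd209d 16.4-fold, the transglutaminase F13a1 13.3-fold, Folr2 12.7-fold and Cbr2 12.1-fold (3.60 ± 0.25, adjusted p = 5.4e-06). Of the myeloid list 5 of 18 rose (9 adjusted over the list alone; adjusted p = 0.206 with an estimated correlation) and of the stellate list 2 of 15, with Acta2 11.5-fold higher (4 adjusted over the list alone; adjusted p = 0.232 with an estimated correlation). Stc1 fell by 3.41 ± 0.48 and Il6 fell by 3.14 ± 0.66 (adjusted p = 0.00196 and 0.0218), with Pvr, Bnip5 and the fibrinogen gene Fgb at log2 fold changes of -2.96 to -2.70 (Fgb -1.97 without chow TRAF2 knockout 1). Immediate early genes were lower as a list (4 of 12 fell, and 7 adjusted over the list alone; adjusted p = 0.206 with an estimated correlation), as were NF-kB genes (3 of 17, and 8 adjusted over the list alone; adjusted p = 0.206 with an estimated correlation). In all, 6 lists were higher and 7 lower at the preset correlation, and the other 9 had adjusted p from 0.206 to 0.587 with an estimated correlation. Limma called 435 genes, 196 higher and 239 lower. It called 1041 with the acinar score, 705 with the ductal score and 732 without the lymphocyte-rich arrays. It called 218, 149 and 123 without HFD TRAF2 knockout 1, 2 and 3 127 without chow TRAF2 knockout 3, 657 without HFD TRAF3 knockout 3 and 741 without chow control 1, and 17 of 36 named genes kept their call whichever array was left out.

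In TRAF3 knockout islets the diet comparison had another content. Interferon-stimulated genes were lower on HFD in 20 of 22 (21 adjusted over the list alone; adjusted p = 3.43e-31, and adjusted p = 0.0471 with an estimated correlation), and Irf7 fell by 4.41 ± 0.54 (adjusted p = 0.000344) from 11.04 ± 0.04 to 6.63 ± 0.31. Serpina3n fell by 4.66 ± 0.81, and Oas1g, Fgg and Fgb had log2 fold changes of -4.30 to -3.84. Beta cell genes were higher on HFD in 10 of 29 (12 adjusted over the list alone; adjusted p = 0.376 with an estimated correlation), Slc2a2 by 6.10-fold and Mafa by 3.91-fold. Of the immediate early genes 9 rose and 1 fell (10 and 1 adjusted over the list alone; adjusted p = 0.376 with an estimated correlation), with Fosb 32.1-fold, Npas4 23.4-fold and Atf3 7.22-fold higher, beside Tph1 at 9.16-fold and Rsph4a at 7.20-fold. Without HFD TRAF3 knockout 3 the log2 fold changes of Fosb and Npas4 were 5.99 and 5.36. Antigen processing genes fell in 10 of 17 and rose in 3 (11 and 4 adjusted over the list alone; adjusted p = 0.376 with an estimated correlation). Retnla read 4.70 ± 0.17 on chow and 4.11 ± 0.71 on HFD, and the myeloid list did not pass (adjusted p = 0.673; 1 of 18 fell, and 1 adjusted over the list alone). Of the 115 genes called in the same direction by diet in controls and in TRAF2 knockouts, 64 had that direction in TRAF3 knockouts, where 11 were called in it and 9 in the opposite one. Ductal markers were lower on HFD by 0.71 ± 0.31 (1 of 10 fell, and 1 adjusted over the list alone; adjusted p = 0.376 with an estimated correlation). Another 11 lists passed at the preset correlation, with adjusted p from 0.376 to 0.622 with an estimated correlation. Limma called 1923 genes, 590 higher and 1333 lower. It called 608 with only the 6 arrays compared in the fit and 443 with the ductal score, of which 409 were among the 1923, and all 1923 kept their sign with a median size of 0.62 (median SE 0.19) against 0.77 (0.17). It called 1228 and 877 without HFD TRAF3 knockout 1 and 2, and 902 and 618 without chow TRAF3 knockout 1 and 3, and 26 of 56 named genes kept their call whichever array was left out.

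Whether the knockout effect depends on the diet was tested by the interaction. For TRAF3 it passed for 1287 genes, 558 with a more positive effect on HFD and 729 with a more negative one. Fosb had the largest positive interaction (6.97 ± 1.40, adjusted p = 0.013), followed by Npas4 and Tph1, and Ms4a6d, a gene of myeloid cells, had the largest negative one (-5.25 ± 1.02, adjusted p = 0.0119), with Retnla at -4.96 ± 0.57 (adjusted p = 0.00129). Without HFD TRAF3 knockout 3, Fosb was at 7.96 and Ms4a6d at -4.58. Of the interferon list 16 of 22 were more negative on HFD (19 negative and 1 positive adjusted over the list alone; adjusted p = 0.147 with an estimated correlation), of the antigen processing list 9 of 17 (10 adjusted over the list alone; adjusted p = 0.335 with an estimated correlation) and of the myeloid list 6 of 18 (8 adjusted over the list alone; adjusted p = 0.335 with an estimated correlation). Immediate early genes were more positive in 8 of 12 (11 adjusted over the list alone; adjusted p = 0.172 with an estimated correlation). So were 4 of 29 beta cell genes, Mafa (2.23 ± 0.48), Slc30a8, Pdx1 and Pax6 (17 adjusted over the list alone; adjusted p = 0.377 with an estimated correlation). Another 6 lists passed at the preset correlation, with adjusted p from 0.147 to 0.542 with an estimated correlation. The count was 681 and 1963 without HFD TRAF3 knockout 2 and 3, 614 and 414 without chow TRAF3 knockout 1 and 3, 851 and 730 without HFD control 2 and 3, and 714 without chow control 2. For TRAF2 limma called 0 genes, with 628 at an unadjusted p under 0.05, and 1 with the ductal score as a covariate; 10 lists passed at the preset correlation and none with an estimated one (adjusted p from 0.738 to 0.756).

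Averaged over diets, TRAF2 and TRAF3 knockouts differed in 61 genes by limma. Bst2 was lower in TRAF2 knockouts by a log2 difference of -1.64 ± 0.22 (adjusted p = 0.00863), and Il6, Irf7, the heat shock gene Hspa1b and Ccl2 by -2.64 to -1.88. Retnla (1.89 ± 0.29, adjusted p = 0.0173), F13a1, Cbr2, the macrophage receptor Vsig4 and Plekhh2 were higher. These averages can hide differences between the diets. Retnla was lower in TRAF2 than in TRAF3 knockouts on chow (3.56 against 4.70) and higher on HFD (9.02 against 4.11). The mean interferon list score was 0.096 in TRAF2 and 1.849 in TRAF3 knockouts on chow, and -0.54 and -0.493 on HFD. Of the interferon list 8 of 22 were lower in TRAF2 knockouts (18 adjusted over the list alone; adjusted p = 2.87e-25, and adjusted p = 0.0975 with an estimated correlation), and the NF-kB list was lower with 0 of 17 passing by limma over all genes and 10 adjusted over the list alone (adjusted p = 0.198 with an estimated correlation). The lactogen list was higher in TRAF2 knockouts by 0.56 ± 0.23, with 0 of 12 passing by limma on either count (adjusted p = 0.313 with an estimated correlation). The myeloid list was higher in TRAF2 knockouts with 0 of 18 passing by limma over all genes and 4 adjusted over the list alone (adjusted p = 0.00135, and adjusted p = 0.456 with an estimated correlation). Another 8 lists passed at the preset correlation, with adjusted p from 0.198 to 0.655 with an estimated correlation. Of the 61 genes 20 were higher and 41 lower in TRAF2 knockouts. The count was 28 with array medians centred, 10 over every probe set, 500 with the acinar score, 1 with the ductal score, 378 without the lymphocyte-rich arrays and 439 without chow control 3 and chow TRAF2 knockout 1. With the ductal score all 61 kept their sign, with a median size of 0.73 (median SE 0.15) against 0.84 (0.15). Limma called 8, 11 and 7 without HFD TRAF2 knockout 1, 2 and 3, 419, 9 and 12 without chow TRAF2 knockout 1, 2 and 3, 9 without HFD TRAF3 knockout 1, and 8, 29 and 11 without chow TRAF3 knockout 1, 2 and 3. It called 33 and 32 without HFD control 1 and 2 and 136 and 34 without chow control 1 and 3. Bst2, Cbr2 and F13a1 were the 3 of 13 named genes that kept their call whichever array was left out.

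How far the knockout effects were shared was measured by correlation across genes, which are not independent replicates. For pairs without a common control, the chow TRAF2 and HFD TRAF3 effects had r = 0.415 and the chow TRAF3 and HFD TRAF2 effects r = 0.164, a mean of 0.289. The TRAF2 effects on chow and on HFD had r = 0.467 and the TRAF3 effects r = 0.0886. Of the genes higher in the chow TRAF2 knockout, 41 of 62 were also higher in the HFD TRAF3 knockout, where 1.04 would be shared by chance if calls were independent, and of the 54 higher in the HFD TRAF2 knockout 24 were higher in the chow TRAF3 knockout (3.42 by chance). Between the TRAF3 knockouts on chow and HFD, 77 genes were higher in both (23.6 by chance) and 29 went opposite ways. All comparisons use the same variance estimate of each gene, so calls are not independent even without an effect, and these chance counts are a rough guide. The labels list Cre in every knockout and do not say whether any control carries it. An effect of Cre could therefore give part of this sharing and cannot be told apart from the deletions. Within a diet the knockouts share controls, which alone gives a correlation: r was 0.658 on chow against 0.502 in simulated data without effects, with a covariance of 0.0964 against 0.0276, and 0.506 on HFD, which is 0.00638 above the simulated value, with a covariance of 0.0542 against 0.0275. Without chow TRAF2 knockout 1 and 3 in turn the mean of the unshared pairs was 0.348 and 0.206, and it was 0.228 without HFD TRAF3 knockout 2, 0.238 without HFD control 1 and 0.251 without chow control 1.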

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

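The tests of other splits and of the patterns weighed here were chosen after the results were seen, except the 2 tests of unequal sex, which were chosen before.

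The TRAF3 knockout effect differed between diets in 1287 genes by the interaction test, which is why it is listed. The largest positive log2 differences (effect on HFD minus effect on chow) were 6.97 for Fosb, 6.45 for Npas4, 4.61 for Tph1, 4.60 for Rsph4a and 4.40 for Atf3. The largest negative ones were -5.25 for Ms4a6d, -4.96 for Retnla, -4.89 for Gpnmb, -4.86 for Pf4 and -4.85 for Ifi204. Without HFD TRAF3 knockout 3 these were 7.96 for Fosb, 7.26 for Npas4 and -4.58 for Ms4a6d, and without chow control 1 they were 5.30 for Tph1, 5.26 for Rsph4a and 5.37 for Atf3. Tph1 was at 5.32 and 3.22 without chow control 2 and 3, and Gpnmb between -5.59 and -4.30 without HFD TRAF3 knockout 1, HFD control 1 or HFD control 3. The TRAF2 and TRAF3 knockouts differed from each other in 61 genes when averaged over diets. The log2 differences, TRAF2 minus TRAF3, were 1.89 for Retnla, 1.78 for F13a1, 1.40 for Cbr2, 1.39 for Vsig4 and 1.33 for Plekhh2, and -2.64 for Il6, -1.98 for Irf7, -1.97 for Hspa1b, -1.88 for Ccl2 and -1.64 for Bst2. For Retnla the diets went opposite ways, with TRAF2 knockouts lower than TRAF3 knockouts on chow (3.56 against 4.70) and higher on HFD (9.02 against 4.11). Among the 16010 probe sets without a gene symbol here, which the main comparisons left out, 49 passed in both knockouts against control, 35 higher and 14 lower.

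Genes that were high in knockouts were also high in chow control 3. The 49 genes higher in both HFD knockout comparisons were chosen by contrasts without a chow group, though the chow arrays entered the pooled spread. Of them, 79.6% were above both other chow controls in this array, against 36.4% over all genes. For the position and the implied share, 38 of them were kept by a log2 margin between the chow TRAF2 knockouts and the other chow controls. Their median position between the other chow controls and the chow TRAF2 knockouts was 0.439 ± 0.0332 (SE, 38 genes), against 0.774 or more in the TRAF2 knockout and HFD TRAF3 knockout arrays, and its interferon list score was lower by 2.15 than in the lowest of the chow TRAF3 knockouts, which stood at 53.4 to 66.6% on that scale. The interferon score argues against a complete exchange with a chow TRAF3 knockout. The arrays at 0.774 or more chose these genes or set the scale, so they stand high partly by construction. The position alone therefore cannot decide on an exchange with such a sample. The beta cell list score of chow control 3 was lower by 0.526 than in the higher of the other chow controls, which argues against a larger share of beta cells. Some material from Cre-positive islets may have entered this sample, but 79.6% lies between the values that would decide it, and the implied share (median 24.7%, quartiles 16.6 and 34.2%) varied between genes. Whether this control carries Cre is not stated, and no biological explanation other than the share of beta cells was tested.

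Lactogen responsive genes were higher in both knockouts, with a median log2 fold change of 1.44 over both diets. On HFD the NF-kB list was 0.65 ± 0.18 higher in TRAF3 than in TRAF2 knockouts while the lactogen list differed by -0.21 ± 0.22, and in TRAF2 knockouts it was 1.72 ± 0.18 (jackknife SE) above a rise in proportion to the NF-kB response, which argues against that proportion there. A weaker grading stays open, as does grading on chow, where the lactogen list was lower in TRAF3 knockouts (-0.90 ± 0.30 SE) but the NF-kB list differed by 0.21 ± 0.15 and the beta cell list score was -0.574 against -0.036. With the sex score in the fit the median was 1.38, which argues against unequal sex of the samples. The Cre transgene itself could give the 1.44 as well and cannot be told apart from the deletions, since the labels list Cre in every knockout, do not say whether any control carries it, and do not say whether the Cre line holds a growth hormone minigene.

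The TRAF3 knockout effect differed between diets. A lower share of beta cells in the chow TRAF3 knockout islets would raise all other cell markers, and other islet endocrine markers changed by -0.52 ± 0.14 while ductal and adipocyte markers changed by 0.85 ± 0.31 and 0.30 ± 0.12, which argues against a loss of beta cells with the other endocrine cells kept. Part of the endocrine and ductal changes rests on chow control 1. It had scores of 0.497 and -0.976 in these lists, against -0.064 to 0 and 0.195 to 0.33 in the other chow controls. A loss of beta and endocrine cells together stays open. The 1 list that fell by over 2 standard errors was the endocrine list, whose fall such a loss would give too, so it does not count against it. Islets taken at another time of day might also differ in this way, and the test did not decide: the arms of the circadian clock had median interactions of 1.48 and 0.19, a gap of 1.30. With the sex score in the fit 1233 genes were called, which argues against unequal sex with an effect alike in all groups. The HFD controls were all female arrays, so a sex effect that differs between groups could not be tested. On the 115 diet-responsive genes the HFD TRAF3 knockouts stood at 0.208 and the chow ones at 0.134, from 0 (chow) to 1 (HFD). Of these genes 62 were called in the interaction, which shares control arrays with their choice. Feeding or preparation apart from the other HFD groups could therefore give part of the interaction and cannot be told apart by the design. So could preparation of the HFD controls and HFD TRAF2 knockouts apart from all other arrays. The diet named by the design remains an untested biological explanation.

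Other splits of the 6 arrays of a comparison are too few for a share under 0.05, since there are 10 with the real one. The real count was 66 and the highest other count 0 for the chow TRAF2 knockout, 2445 and 0 for the chow TRAF3 knockout, 56 and 12 for the HFD TRAF2 knockout, and 560 and 25 for the HFD TRAF3 knockout. It was 196 and 2 for the diet in controls, 435 and 0 in TRAF2 knockouts and 1923 and 0 in TRAF3 knockouts. In each, the real split was the 1 that gave as many genes. For both knockouts against control, the real split was the 1 of 100 that gave as many (622, highest other 378). Chance without any difference between the genotypes is therefore unlikely to give this count. The 16 gene lists of that comparison were reached by 6 of 100 splits (highest other 19), so chance cannot be excluded there. For the TRAF2 and TRAF3 knockouts compared, 3 of 100 splits gave as many as the 61 genes. The share is under 0.05 for no difference between them on either diet, by a small margin, since other splits gave more genes (highest 249). Splits of this kind also break up any difference that holds on 1 diet only. They cannot decide whether chance gives the difference averaged over diets. For the TRAF3 interaction 3 of 100 splits gave as many as the 1287 genes (highest other 1810). Those splits exchange knockout and control arrays within a diet and so break up the knockout effect itself. They therefore cannot decide whether chance gives the interaction. For the TRAF2 interaction limma called 0 genes (628 with an unadjusted p under 0.05), a count that all 100 splits had to reach, so the splits say nothing about chance there; the highest other count was 199. Splits that call 249 genes against 61, or 199 against 0, point to some structure of the samples, which was not tested, and the arrays exchanged in them also differ in genotype.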

How the results depend on the processing

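The ductal score as a covariate, leaving out the lymphocyte-rich arrays, and leaving out chow control 3 with chow TRAF2 knockout 1 were chosen only after the results were seen.

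Of the main counts and values, 122 alternatives other than leaving out 1 array stayed within 1.5 times the count or within the spread, and 36 did not. Quantile normalization applied again and eBayes with trend and robust moved none of them beyond that. Named genes kept their direction and their side of the threshold in 3960 of these alternatives, lost the call in 506 and turned in 1, and gene lists did so in 1620, 414 and 8. With 1 of the 18 arrays left out the numbers were 5670, 1091 and 7 for genes and 2466, 154 and 8 for lists. Where an array was left out, the groups of 2 left were assumed to vary like the others. Signals near the background of the array limit what dim genes can show, and the filter on them left 11090 genes.

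With dim genes left out, the diet in controls gave 306 genes and the mean agreement of the unshared pairs was 0.325, against 0.289. With array medians centred, TRAF2 against TRAF3 knockouts gave 28. With only the samples compared in the fit, limma called 0 in the chow TRAF2 knockout (1429 unadjusted with all arrays), 144 in the HFD TRAF3 knockout, 78 for the diet in controls and 608 in TRAF3 knockouts, with fewer arrays to estimate the spread. Over every probe set, TRAF2 against TRAF3 gave 10 and the agreement was 0.213. With the sex score, the diet in controls gave 48, although all 196 genes kept their sign with a median size of 1.07 against 1.11, and the agreement was 0.330. With the acinar score, the chow TRAF3 knockout gave 4150, the HFD TRAF3 knockout 873, both knockouts 1322, the diet 382 in controls and 1041 in TRAF2 knockouts, and TRAF2 against TRAF3 500. With the ductal score, the chow TRAF2 knockout gave 100, the chow TRAF3 knockout 190, the HFD TRAF2 knockout 102, the HFD TRAF3 knockout 890 and both knockouts 282. The diet then gave 831 in controls, 705 in TRAF2 and 443 in TRAF3 knockouts, the TRAF2 interaction 1, TRAF2 against TRAF3 1, and the agreement was 0.375. All genes called without that score kept their sign, with a median size of 0.56 against 0.65 in both knockouts and 0.73 against 0.84 in TRAF2 against TRAF3. Without the lymphocyte-rich arrays, the HFD TRAF3 knockout gave 367, the diet 466 in controls and 732 in TRAF2 knockouts, TRAF2 against TRAF3 378, and the agreement was 0.329. Without chow control 3 and chow TRAF2 knockout 1, TRAF2 against TRAF3 gave 439. Of the 16 lists in both knockouts, 2 passed with an estimated correlation and 10 by fry. Part of the agreement of the knockouts within a diet may come from their shared controls, which with 3 arrays could not be divided into groups of 2. Apart from the fit of only the samples compared, the cause was not tested.

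Replicate numbers did not pair the arrays: 8 of 18 arrays correlated best with the same number, and the median correlation after removing group means was 0.029 for the same number and -0.032 for others. With the replicate block the counts were 55, 2590, 58, 546 and 627 for the chow TRAF2, chow TRAF3, HFD TRAF2, HFD TRAF3 and combined knockouts, and 189, 434 and 1942 for the diet in controls, TRAF2 and TRAF3 knockouts. They were 0 and 1366 for the TRAF2 and TRAF3 interactions and 51 for TRAF2 against TRAF3, with 16 lists and an agreement of 0.289.

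Leaving out each of the 18 arrays in turn gave ranges of 10 to 89 genes for the chow TRAF2 knockout, with the lowest without chow TRAF2 knockout 3, and 786 to 3016 for the chow TRAF3 knockout, without chow TRAF3 knockout 3 and HFD TRAF3 knockout 3. The HFD TRAF2 knockout ranged from 20 (without HFD control 3) to 92 (without HFD TRAF3 knockout 3) and the HFD TRAF3 knockout from 249 (without HFD TRAF3 knockout 2) to 806 (without chow control 1). Both knockouts ranged from 342 (without chow control 1) to 865. The diet in controls ranged from 19 (without chow control 2) to 603 (without chow control 1), in TRAF2 knockouts from 123 (without HFD TRAF2 knockout 3) to 741 (without chow control 1) and in TRAF3 knockouts from 618 (without chow TRAF3 knockout 3) to 2466. The TRAF2 interaction stayed at 0 by limma, with 628 genes unadjusted when all arrays were used. The TRAF3 interaction ranged from 414 (without chow TRAF3 knockout 3) to 1963 (without HFD TRAF3 knockout 3), TRAF2 against TRAF3 from 7 (without HFD TRAF2 knockout 3) to 419 (without chow TRAF2 knockout 1) and the agreement from 0.206 (without chow TRAF2 knockout 3) to 0.348 (without chow TRAF2 knockout 1). The report names the other arrays that moved a count by over 1.5 times. Lists in both knockouts ranged from 16 to 17.

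Some list tests turned, given here as list medians on the log2 scale. Under the acinar score the acinar list itself turned to 0.0319 in the chow TRAF3 knockout, 0.0078 in both knockouts, -0.0743 for the diet in controls and 0.00066 in TRAF2 against TRAF3, and under the ductal score the ductal list turned to 0.17 for the diet in TRAF3 knockouts. These scores are made of the same genes, so their own list is removed by construction. The interferon list turned in the TRAF2 interaction to 0.0821 without the lymphocyte-rich arrays and, by the direction of the test, at -0.0152 without chow control 3 and chow TRAF2 knockout 1, and at 0.0460 in the chow TRAF2 knockout without that pair. With 1 array left out it ranged from -0.50 to 0.0821 in the interaction, turning without chow TRAF2 knockout 1. Without that array the proliferation list turned in the chow TRAF2 knockout (range 0.0250 to 0.529). Without chow control 1 the other endocrine list turned there (-0.257 to 0.0560) and the ER stress list in the TRAF2 interaction (-0.30 to 0.0323). Without HFD control 3 the endothelial list (-0.0613 to 0.399) and the lipogenesis list (-0.0454 to 0.260) turned in the HFD TRAF2 knockout. Without HFD TRAF3 knockout 3 the stellate list turned in the HFD TRAF3 knockout (-0.49 to 0.34), and without HFD TRAF3 knockout 2 the acinar list in TRAF2 against TRAF3 (-0.0332 to 0.408). The cause was not tested. Traf2, which passed nowhere, turned to -0.0242 in the chow TRAF2 knockout without chow control 3 and chow TRAF2 knockout 1. With 1 array left out it ranged from -0.0062 to 0.28 in the HFD TRAF2 knockout, from -0.14 to 0.14 in the TRAF2 interaction and from -0.0512 to 0.233 in the TRAF3 interaction, each lowest without HFD control 3. In the TRAF2 interaction it was also -0.0386 without HFD TRAF2 knockout 2, -0.0047 without chow TRAF2 knockout 2, -0.0108 without chow TRAF2 knockout 3 and -0.0423 without chow control 2.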

Other observations

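The test of exchanged or missing diets given here was chosen after the result was seen.

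Chow TRAF2 knockout 1, the 1 female array of its group, read close to the chow TRAF3 knockouts, of which 1 is female, in several genes. It read 11.19 for the acute phase gene Serpina3n, where the other chow TRAF2 knockouts read 6.98 and 7.62 and the chow TRAF3 knockouts 10.86 to 11.67. The platelet and macrophage chemokine Pf4 read 8.50 against 5.46 and 5.08, and 7.86 to 8.16 in the chow TRAF3 knockouts. Slc2a2 read 8.49 against 10.84 and 11.16, and 7.99 to 9.05 in the chow TRAF3 knockouts. Interferon-stimulated genes lay between: Irf7 read 9.26 and Bst2 6.85, against 10.99 to 11.08 and 9.02 to 9.24 in the chow TRAF3 knockouts. Without this array the median log2 fold change of the interferon-stimulated genes list, chow TRAF2 knockout minus control, was -0.00351, against 0.41 with it.

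The nuclear long non-coding RNAs Neat1 and Malat1 had higher means in HFD TRAF3 knockouts than in both other HFD groups, which read alike. The difference of Malat1 from HFD controls did not pass by limma. Neat1 (probe set 17361805) read 6.14 ± 0.17 (SD, n = 3) in HFD controls and 6.10 ± 0.03 in HFD TRAF2 knockouts, and 7.85 ± 0.44 in HFD TRAF3 knockouts, against 7.63 to 8.44 as group means on chow. Malat1 read 9.79 ± 0.14, 9.76 ± 0.07 and 10.52 ± 0.11 in the same HFD groups and 10.61 to 11.05 on chow. It fell on HFD in controls and in TRAF2 knockouts (adjusted p = 0.0316 and 0.013), and in TRAF3 knockouts the change was -0.09 (adjusted p = 0.885). Its TRAF3 interaction did not pass (adjusted p = 0.0705), while that of Neat1 did (adjusted p = 0.00585). Among female arrays Xist read 9.07 to 9.42 in HFD controls and HFD TRAF2 knockouts, 10.15 and 10.45 in HFD TRAF3 knockouts and 9.94 to 11.28 on chow.

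Between HFD and chow, 115 genes differed in the same direction in controls and TRAF2 knockouts, 76 higher and 39 lower on HFD. They were chosen by contrasts that hold no TRAF3 knockout group. The TRAF3 knockout arrays still entered the choice through the pooled spread, so it was not fully independent of them. On a scale from 0 (chow) to 1 (HFD) set by the other genotypes, the HFD TRAF3 knockout arrays stood at 0.270, 0.299 and 0.0736 and the chow ones at 0.208, 0.137 and 0.181. The median position of the chow group was 0.134 ± 0.0340 (SE over genes, which are not replicates), and the HFD group stood only 0.0720 ± 0.0407 above it. An exchange of diet labels between the TRAF3 knockout groups would put the chow group near 1 only if TRAF3 knockouts responded to the diet as the other genotypes did. Since neither group stood near 1, the test cannot decide on an exchange. The small difference between the TRAF3 knockout groups has several possible sources. It may be an effect of the deletion on the response to the diet, or the HFD TRAF3 knockout mice or samples may have been fed or prepared apart from the other HFD groups. The HFD controls and HFD TRAF2 knockouts may also have been prepared apart from all other arrays, and the design cannot tell these apart. Body weights and feeding records of the HFD TRAF3 knockout mice would bear on their feeding. A new cohort with all 3 genotypes on both diets, prepared side by side, would decide between them.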
